A study of Solanum chacoense with 24 samples.

How the data were processed

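Leaf RNA of Solanum chacoense was sequenced. Per the labels' protocols, RNA was isolated from leaflets 16 weeks after transplanting, from plants kept at 20 °C with 16 h of light per day and 70% relative humidity, and every sample had an RNA integrity number of at least 8. The 24 libraries came from 8 lines with 3 plants each, and by the labels the plants of a line came from in vitro culture of 1 individual, so that they would share a genotype. In parental state, defined below, the plants of EE501F2_641 stood apart from each other by more than plants of the other lines. Whether they share a genotype is open. Lines were put in the resistant or the susceptible class as the labels give Colorado potato beetle resistance.

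The authors deposited 1 table of raw counts per gene model. Per the submitters' processing notes, the tools used were Trimmomatic 0.35, STAR 2.6.0, featureCounts 1.5.3, Subread and DESeq2, with no role or order given, and per the file headers the columns of the table are those that featureCounts writes. The counts are whole numbers and had not been normalized. The columns of the deposited table that hold counts carry names ending in merged alignments, 1 column per library, and no column was left unmatched to a library. The table also gives each model's length in bases, a unit other than counts that the authors deposited and that entered no test. The genome build, the annotation release, the treatment of multi-mapping reads and the strand setting are not given in the sources used here. Coordinates are printed as the table gives them, counted from 1, with the outermost exon ends as start and end. Reads from near-identical copies and from antisense neighbours could therefore not be separated from those of the named models; none of the named models overlapped another model in coordinates.

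The table held 37740 gene models, 29786 of them on 12 chromosomes. The other 7954 lay on a sequence named as unplaced and had 0 counts in every library, which was taken as a property of the counting and not as lack of expression. On the chromosomes, 3367 models had 0 counts in every library. The total count per library ran from 23610756 to 77078776. Line EE501F2_093 was the deepest, with at least 60713423 per library, and libraries of the other 7 lines had at most 40825791. A count of 0 over the 3 libraries of a parent allows up to 3 counts, which was 0.0284 CPM (counts per 1000000 of the library's total after TMM scaling) in M6 and 0.0409 CPM in 80-1. Floors and counting intervals (95%) cover counting error only. Replicates within a line differed by more than counting noise: the chi-square per degree of freedom ran from 11.7 to 233 over the 24 pairs, where counting noise alone gives 1, so every library was kept as its own replicate.

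Counts were analysed in R 4.3.3 with edgeR 4.0.16. Models with low counts were removed with filterByExpr, which left 21028 for tests between plants. Library sizes were scaled by TMM, and CPM values are TMM-normalised unless stated otherwise. A quasi-likelihood model with 1 mean per line was fitted to all 24 libraries (16 residual degrees of freedom), p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The contrast of the parents was 80-1 minus M6. For the F2 generation, where the line is the replicate of a class, counts were summed over the 3 plants of each line, and 3 resistant lines were tested against 3 susceptible lines on 21184 models (4 residual degrees of freedom). The mean of the resistant line means minus the mean of the susceptible line means was also tested on plants. Another criterion asked for a call with the same sign in all 9 pairs of 1 resistant and 1 susceptible line. These last comparisons rest on the spread between plants and speak only of these 6 lines. Log2 fold changes are edgeR estimates. Errors beside them are approximate standard errors, the absolute estimate divided by the square root of the F statistic.

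Calls were counted per chromosome and in 5 Mb windows with Fisher's exact test (two-sided, adjusted over chromosomes or windows). A parental state index was computed for genes with a parental adjusted p under 0.05 and an absolute log2 fold change of at least 2: the line's mean log2 CPM (prior count 2) minus that of M6, divided by the difference of 80-1 and M6. An index of 0 is the M6 level and 1 the 80-1 level, and medians were taken over windows with at least 5 such genes.

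The identifiers are not paired with gene names or descriptions in the sources used here. The 24 gene lists fixed beforehand (glycoalkaloid enzymes, proteinase inhibitors, jasmonate genes, markers of other tissues and others) could therefore not be tested. By the rule fixed before the data were examined, the 2 models with the largest rise and the 2 with the largest fall are named per comparison, among called models with at least 5 CPM in the higher group. For genes changed in parents and F2 alike, the 2 per direction with the smallest worst-pair adjusted p are named. Further regions are given by coordinates and were chosen after their values were seen.

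The steps were tested on simulated counts for 21028 models drawn from the measured means, dispersions and library sizes, with 200 models changed. The parental contrast recovered 40% of 100 models changed 2-fold and 89% of 100 changed 4-fold, with 7 false calls. In simulated F2 lines each gene varied independently of its neighbours, unlike the linked genes of a real F2. The SD was that of measured line means within classes, which already holds some spread between plants. The test on summed lines recovered 42% of 100 models changed 4-fold and 71% of 100 changed 16-fold, with 4 false calls. The criterion of 9 pairs recovered 70% and 89% of them, with 71 false calls, and the test on the mean of plants recovered 99% of each with 5916 false calls. With 100 of the changed models placed on chromosome 2, that chromosome was the 1 found over-represented, and 1 other was found under-represented.

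Alternatives were size factors of the DESeq2 kind, no filter or a stricter filter (1 CPM in 3 libraries), a minimum of 2-fold, DESeq2 1.42.0, only the libraries compared, a replicate block, limma-voom (limma 3.58.1) with the line as a random effect, each replicate and each F2 line left out, and other windows and fold minimums for the index.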

Results

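Leaf transcriptomes were compared in a cross between 2 lines of Solanum chacoense, a wild diploid relative of potato. The parent 80-1 resists the Colorado potato beetle, an insect that feeds on potato leaves, and the inbred parent M6 is susceptible. From their F2 population, 3 resistant lines (EE501F2_089, EE501F2_516 and EE501F2_641) and 3 susceptible lines (EE501F2_093, EE501F2_099 and EE501F2_500) from the extremes of a field trial were grown beside the parents in a growth chamber. Each of the 8 lines gave 3 libraries, 1 per plant. Total counts were 23610756 to 40825791 per library, except in EE501F2_093 with 60713423 to 77078776. The 3 plants of EE501F2_641 differed in parental state, a scale from M6 at 0 to 80-1 at 1, more than those of any other line. They lay over 0.4 apart in 35 of 96 windows of 5 Mb, against at most 4 windows in another line. In the principal components of log2 CPM, plants of a line were closer on the second component (SD 0.993 to 5.26) than on the first (SD 5.72 to 35.1, the largest in EE501F2_099). The first component (24.5% of the variance) had EE501F2_516 at one end (120 ± 16.4, SD, n = 3) and 80-1 at the other (-86.4 ± 9.10, SD, n = 3). The second (18.4%) ran from 80-1 (-74.2 ± 1.45) to M6 (113 ± 5.26). All 3 resistant F2 lines had negative means on it, the lowest of them EE501F2_089 (-42.4 ± 4.34), and all 3 susceptible lines had positive means, from EE501F2_500 (2.19 ± 4.43) to EE501F2_099 (37.2 ± 0.993).

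**Figure D1:**
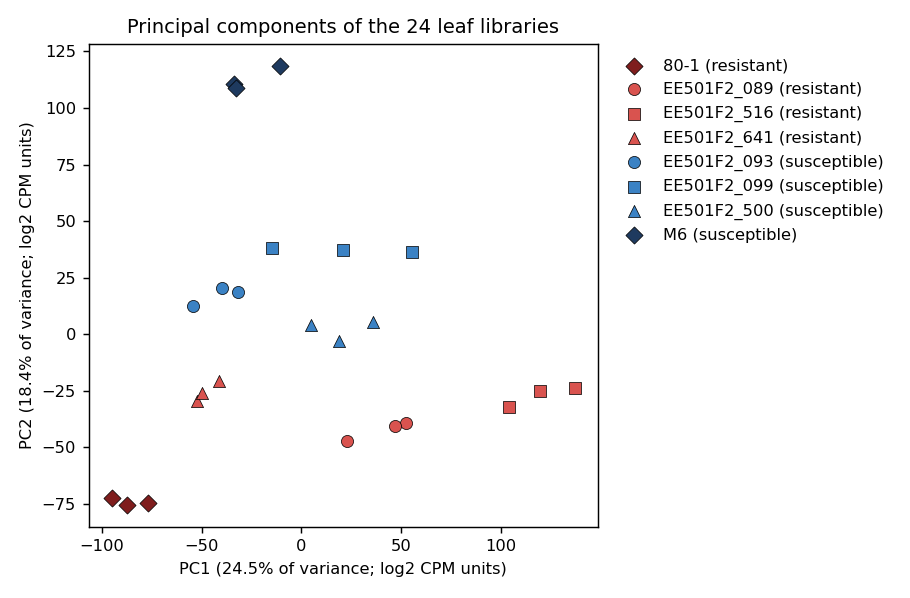
Principal components 1 and 2 of log2 CPM in the 24 libraries, 1 point per plant, with colour for parent and resistance class and marker shape for the line. The axes give 24.5% and 18.4% of the variance, and plants of EE501F2_516 lie farthest from those of 80-1 on the first.

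The parents were compared to find how leaf expression differs between a beetle-resistant and a susceptible genotype. Of 21028 gene models tested, 7847 (37.3%) differed, 3919 higher in 80-1 and 3928 higher in M6, and 4669 of them differed by at least 2-fold. The models with the largest differences were read in 1 parent alone. The model g26016 (chromosome 8, 23398544 to 23400347) reached 21.5 ± 8.94 CPM (SD, n = 3) in 80-1 and had 0 counts in M6, at least 611-fold higher in 80-1 (edgeR adjusted p = 7.08e-05). The model g7648 (chromosome 8, 1645353 to 1645886) stood at 20.1 ± 10.3 CPM in 80-1 with 0 counts in M6, at least 584-fold higher (adjusted p = 3.29e-05). In the other direction, g18288 (chromosome 9, 14175053 to 14181070) had 9.62 ± 0.114 CPM in M6 and 0 counts in 80-1, at least 191-fold lower in 80-1 (adjusted p = 4.26e-09). The model g1277 (chromosome 11, 31807083 to 31812429) had 8.41 ± 3.43 CPM in M6 and 0 counts in 80-1, at least 164-fold lower (adjusted p = 6.14e-06). These bounds are the lower ends of 95% counting intervals of the ratio, which leave out the spread between plants.

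Differences between the parents were spread over the 12 chromosomes. The share of tested models that differed was 41.5% on chromosome 12, 41.1% on chromosome 11 and 40.9% on chromosome 5, each above the rest of the genome (37.0%, 37.0% and 37.1%; Fisher's exact test, two-sided, adjusted p = 0.00478, 0.00764 and 0.0158). Chromosome 2, by contrast, had 35.4% against 37.5% elsewhere, which did not pass the test (adjusted p = 0.122). Parental p-values measure the spread between plants of 1 genotype each, so they speak of these 2 lines.

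Each F2 line was set against each parent to place it between them. Among the resistant lines, EE501F2_089 differed from 80-1 at 8633 genes and from M6 at 8356, and EE501F2_516 at 11543 and 10250. EE501F2_641 differed from 80-1 at 6887 genes and from M6 at 8530. Among the susceptible lines, EE501F2_099 differed from 80-1 at 7807 genes and from M6 at 4393, EE501F2_500 at 8147 and 7008, and EE501F2_093 at 4564 and 4480. The order of the lines depends on the fit: on the 6 libraries compared alone, EE501F2_641 differed from 80-1 at 2799 genes and from M6 at 3808, and EE501F2_093 from 80-1 at 7446. Over the genes with strong parental differences, the median parental state was 0.532 ± 0.0587 (SD, n = 3 lines) in the resistant lines and 0.400 ± 0.0665 in the susceptible lines, on a scale with M6 at 0 and 80-1 at 1. An exact permutation test over lines gave p = 0.1 (two-sided), the smallest value that 3 lines against 3 can give.

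Resistant and susceptible F2 lines were compared to find genes whose expression follows the trait in the segregating generation. With the line as the replicate, 3 of 21184 genes passed the test, all 3 higher in the resistant lines and all 3 higher in 80-1 than in M6. Other splits of the lines gave up to 7 genes, and 2 of 10 splits, the real split among them, gave at least 3. Simulated lines gave 4 false calls in this test. A count of 3 is thus not particular to the resistance classes. Of the 3 genes, g33589 and g33597 lie within 69.5 kb of each other, so their agreement with the parents is not independent. The model g33589 (chromosome 12, 49865983 to 49870302) had 32.8 ± 0.034 CPM (SD of the line means, n = 3) in the resistant lines and 3.89 ± 0.379 CPM in the susceptible lines, a log2 fold change of 3.07 ± 0.18 (adjusted p = 0.0225). Its level was 77.5 ± 4.37 CPM in 80-1 and 4.31 ± 1.03 CPM in M6. The model g33597 (chromosome 12, 49928075 to 49930797) had 8.92 ± 1.72 CPM in the resistant and 0.0474 ± 0.0321 CPM in the susceptible lines, a count ratio of 193 (95% counting interval 122 to 326; adjusted p = 0.0405). The model g3669 (chromosome 2, 7242861 to 7250207) had 7.85 ± 2.06 CPM in the resistant lines and 5 counts in all susceptible libraries together, a ratio of 642 (275 to 1980; adjusted p = 0.0462), with 9.92 ± 0.955 CPM in 80-1 and 0 counts in M6.

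The number of calls depended on the test: DESeq2 called 540 genes on the same sums (796 and 681 in 2 other splits of the lines), and limma-voom with the line as a random effect called 174. At an unadjusted p under 0.05 the edgeR test had 1568 genes, where 1059 are expected by chance, and leaving out EE501F2_641 gave 13 calls, while leaving out any other of the F2 lines gave 0. With 1 plant of EE501F2_641 in place of the sum of its 3, the calls were 3, 12 and 9.

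On the spread between plants, 266 genes differed in the same direction in all 9 pairs of a resistant and a susceptible line, 138 higher and 128 lower in the resistant lines. The largest rise among the named models was at g10223 (chromosome 7, 1822408 to 1823835), with 6.55 ± 2.79 CPM (SD of line means, n = 3) in the resistant lines and 4 counts in all susceptible libraries together, a ratio of 696 (95% counting interval 271 to 2556). The plants of EE501F2_641 had 5.44, 0.218 and 4.78 CPM of g10223. The next largest rise was at g3669. Both models named for the largest falls, among those with at least 5 CPM in the higher group, were on chromosome 2. At g23983 (32488501 to 32490621) the resistant lines had 0.683 ± 0.844 CPM and the susceptible lines 24.5 ± 11.4 CPM, a log2 fold change of -5.80 ± 0.36 (3.77, 0.654 and 0.545 CPM in the plants of EE501F2_641), and 80-1 had 0.146 ± 0.116 CPM beside 86.6 ± 22.4 CPM in M6. At g19481 (36898863 to 36911724) the resistant lines had 1.60 ± 2.35 CPM and the susceptible lines 20.2 ± 4.09 CPM (log2 fold change -4.97 ± 0.38; 0.325, 2.89 and 9.72 CPM in the plants of EE501F2_641), whereas the parents, at 13.6 ± 3.31 CPM in 80-1 and 26.1 ± 3.71 CPM in M6, did not differ (adjusted p = 0.154). The errors of these 2 log2 fold changes rest on the spread between plants. Over lines, the log2 fold change was -5.21 ± 1.03 for g23983 and -3.60 ± 1.21 for g19481. There g10223 (adjusted p = 0.103), g23983 (0.271) and g19481 (0.549) did not pass the edgeR test. DESeq2 called all 3 (adjusted p = 7.15e-20, 1.18e-06 and 0.0270).

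The mean of the resistant plants differed from that of the susceptible plants at 7007 genes (3346 higher, 3661 lower), but another split of the lines gave 10700 and simulated lines 5916 false calls. Line means of the classes did not overlap at 2675 genes (12.7%), where chance gives 10%. In simulated lines, genes that varied without regard to class, and without linkage to each other, gave 71 false calls in all 9 pairs. Another split of the measured lines gave 139. The count of 266 was 83 without replicate 2 of each line and 66 without replicate 3. It was 418, 1252 and 492 in the 6 pairs left without EE501F2_516, EE501F2_641 and EE501F2_500.

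**Figure D2:**
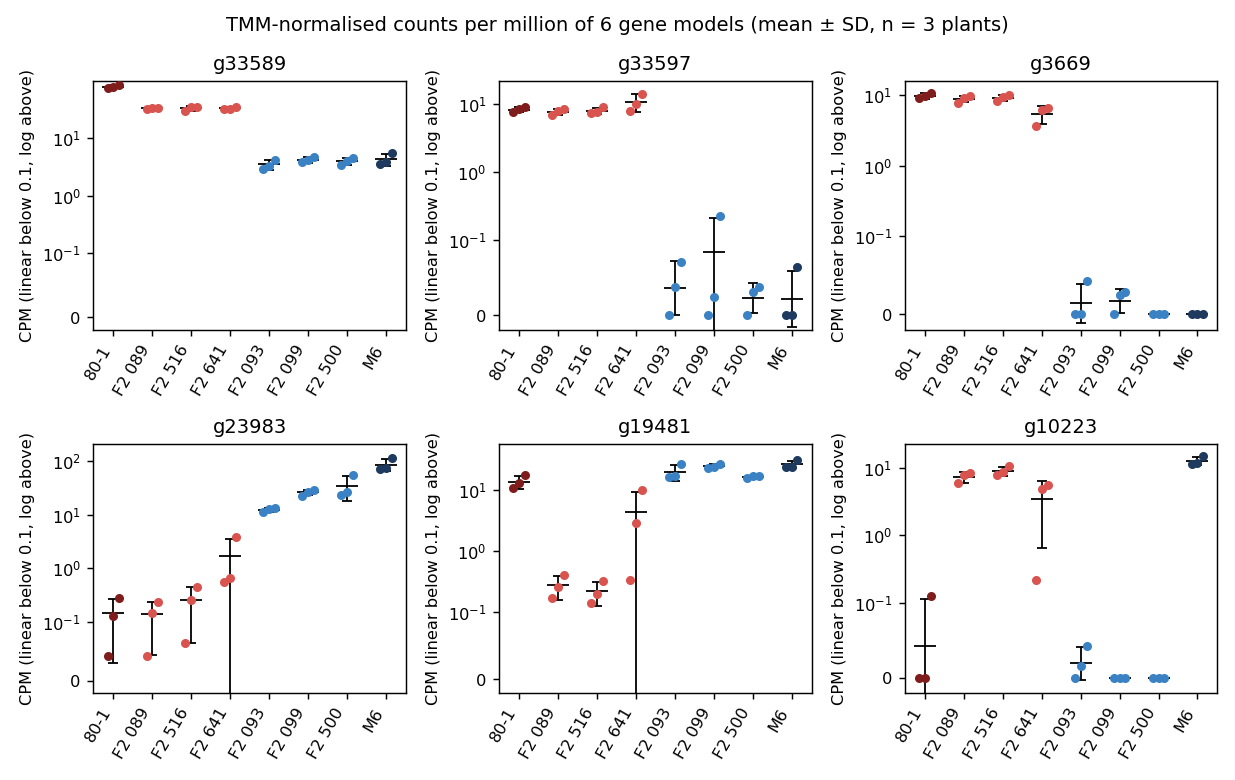
CPM of 6 gene models in the 8 lines, with 1 point per plant and the mean ± SD of 3 plants as bars, cut where they pass the lower end of the axis; the axis is linear below 0.1 CPM and logarithmic above. The models g33589, g33597 and g3669 are high in 80-1 and in each resistant F2 line, and g23983 is low in them. The model g10223 is high in M6 and the resistant lines, except in replicate 2 of EE501F2_641.

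Parents and F2 lines were set side by side to find genes that follow the trait in both generations. Of the 266 genes, 101 changed in the direction of the parental difference, 25 in the opposite direction, and 140 were not called between the parents. The 59 genes higher in both compare with 25.7 expected of independent lists (odds ratio 3.29, 95% interval 2.31 to 4.68; Fisher's exact test, two-sided, adjusted p = 2.52e-10), and the 42 lower in both with 23.9 (odds ratio 2.14, 1.44 to 3.13; adjusted p = 0.000334). Independence is not what an F2 without a link to the trait would give, since loci that differ between the parents are those that segregate. Of the 266 genes 38.0% changed alike, and in 7 of the 9 other splits of the lines the share was larger, up to 31 of 38 genes (81.6%), with the sides of each split ordered to give the larger count. Among the genes higher in both, g33589 and g35199 had the smallest p-values in their worst pair. The model g35199 (chromosome 4, 35875861 to 35876379) had 8.04 ± 1.34 CPM in the resistant lines, 0.0402 ± 0.0286 CPM in the susceptible lines and 15.9 ± 2.92 CPM in 80-1, with 2 counts in M6. Lower in both were g27169 (chromosome 7, 32524552 to 32526186), with 24.3 ± 0.076 against 89.5 ± 19.0 CPM, and g19953 (chromosome 7, 28360737 to 28365560), with 8.58 ± 0.282 against 68.2 ± 29.4 CPM. For both, 80-1 was closer to the susceptible lines, at 73.5 ± 10.3 CPM for g27169 and 56.9 ± 2.29 CPM for g19953, with 120 ± 12.5 and 129 ± 28.3 CPM in M6. Over lines, g35199 (adjusted p = 0.0665), g27169 and g19953 (0.103 each) did not pass the edgeR test. DESeq2 called these 3 (adjusted p = 1.50e-43, 2.37e-13 and 5.50e-13). The count of 101 was 33 without replicate 2, 27 without replicate 3 and 429 in the 6 pairs without EE501F2_641.

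The positions of the changed genes were examined because genes on a segment that segregates in the F2 are inherited together. Chromosome 2 held 54 of the 266 genes, 2.51% of its 2148 tested genes against 1.12% elsewhere (odds ratio 2.27, 95% interval 1.65 to 3.09; Fisher's exact test, two-sided, adjusted p = 1.25e-05). Of these 54 genes, 21 were higher and 33 lower in the resistant lines, and 32 had the direction of the parental difference against 1 with the opposite direction. None of the other 11 chromosomes passed this test. Among the 101 genes changed alike in parents and F2, 32 lay on chromosome 2 (odds ratio 4.12, adjusted p = 3.40e-08) and 16 on chromosome 12 (odds ratio 2.37, adjusted p = 0.0204). In 5 Mb windows, changed genes were over-represented at 20 to 25 Mb of chromosome 2, with 13 of 342 genes (adjusted p = 0.0242), and at 0 to 5 Mb of chromosome 7, with 13 of 304 (adjusted p = 0.0155), 11 of them higher in the resistant lines. Neighbouring genes of an F2 segregate together, and 6 of the 9 other splits of the 6 lines also had a chromosome over-represented. Among these, 23 of 38 genes lay on chromosome 11 (odds ratio 19.6, adjusted p = 4.72e-16) when EE501F2_089, EE501F2_641 and EE501F2_099 were set against the rest, and 41 of 139 on chromosome 4 (odds ratio 4.88, adjusted p = 1.21e-12) when EE501F2_089, EE501F2_641 and EE501F2_093 were. The excess on 1 chromosome is thus not particular to the resistance classes.

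**Figure D3:**
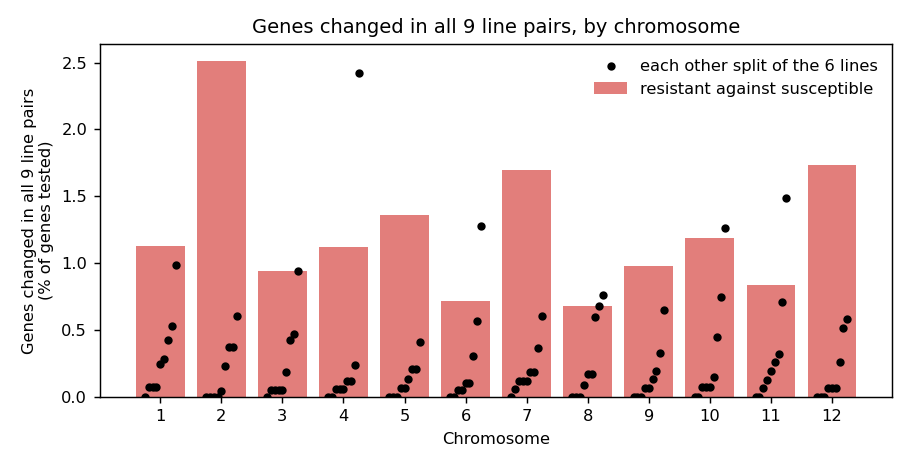
Percent of the tested genes on each chromosome that changed in all 9 line pairs. Bars show the resistant against the susceptible lines, from 0, and points the 9 other splits of the 6 lines into 3 and 3; the bar of chromosome 2 stands at 2.51%, and the highest point, on chromosome 4, at 2.43%.

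Along the chromosomes, the parental state of the F2 lines was followed over 2449 genes with strong parental differences, in 96 windows of 5 Mb. On chromosome 2, every resistant line lay above every susceptible line in 7 of 8 windows, and on the other chromosomes in 5 windows. The gap between the lowest resistant and the highest susceptible line was widest at 5 to 10 Mb of chromosome 2 (0.560), where EE501F2_089 stood at 0.922, EE501F2_516 at 0.970 and EE501F2_641 at 0.695, and the susceptible lines between -0.0693 and 0.135. With each plant of EE501F2_641 taken alone, 5 of the 8 windows kept all 3 of its plants, EE501F2_089 and EE501F2_516 above every susceptible line. Over the 200 such genes of chromosome 2, the median was 0.769 ± 0.0698 (SD, n = 3 lines) in the resistant and 0.386 ± 0.0028 in the susceptible lines (exact permutation test, two-sided, p = 0.1, the smallest possible here; adjusted over 12 chromosomes p = 0.7). In 2 windows every resistant line lay below every susceptible line, 1 of them at 0 to 5 Mb of chromosome 7, with 0.257 to 0.408 in the resistant and 0.479 to 0.848 in the susceptible lines. With the genes changed in all 9 pairs left out, the classes overlapped there, with the susceptible EE501F2_500 at 0.437 and the resistant EE501F2_089 at 0.476.

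**Figure D4:**
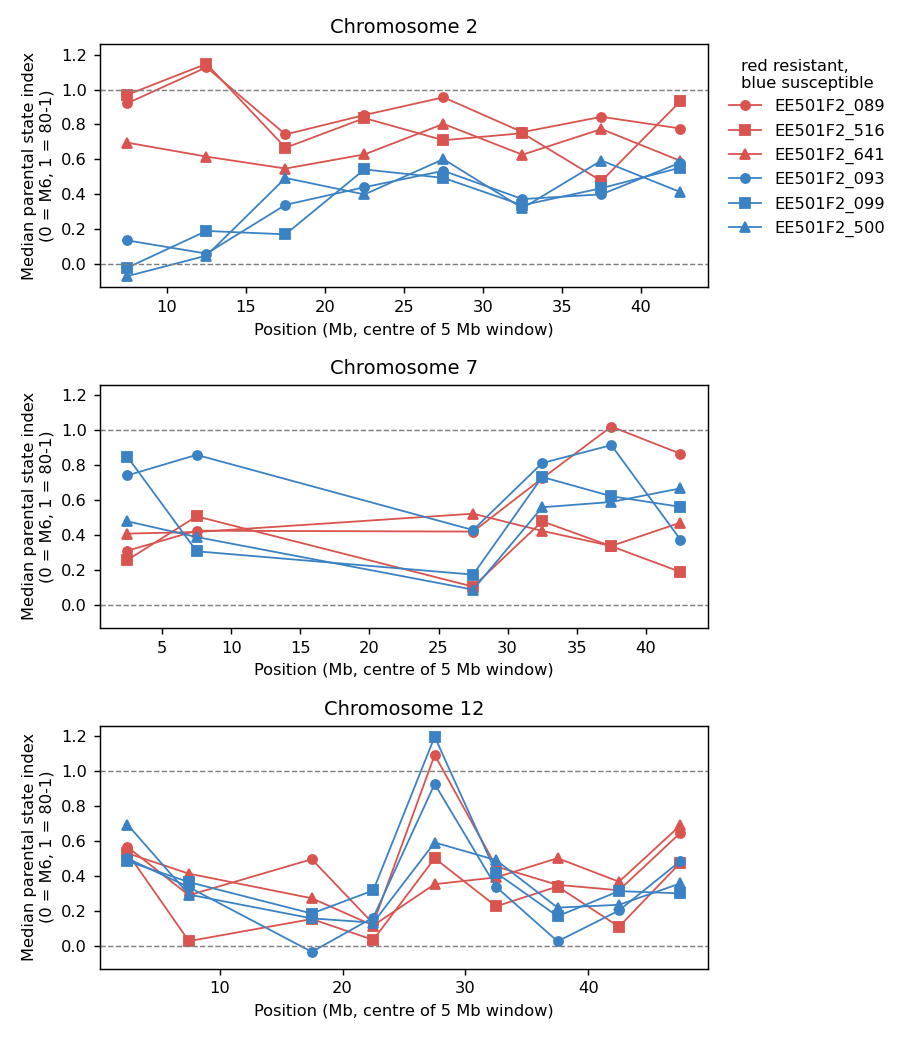
Median parental state index of the 6 F2 lines in 5 Mb windows of chromosomes 2, 7 and 12, where 0 is the level of M6 and 1 that of 80-1 (dashed lines). On chromosome 2 the 3 resistant lines (red) lie above the 3 susceptible lines (blue) in 7 of 8 windows.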

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

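The results here stood out because the difference between 80-1 and M6 and the difference between resistant and susceptible F2 lines were not the same size or not the same direction, by opposite calls or by edgeR's test of the interaction (Benjamini-Hochberg adjusted over 21028 genes, of which 7293 passed). The interaction test rests on the spread between plants and speaks only of these lines. The tests in this part were chosen after the result was seen.

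Of the 266 genes changed in all 9 F2 pairs, 25 were called in the opposite direction between the parents. Genes picked by opposite calls pass the interaction test almost by construction, so it adds nothing for them. They were 17 genes higher and 8 lower in the resistant F2 lines, and 8 of the 25 lay on chromosome 7, all within 0 to 5 Mb. Of these, 6 form a run from 1811685 to 1867251 that includes g10223. For g10223 the parental minus the F2 log2 fold change was -17.94, which depends on the prior count of the fit and is no measure of size, since counts were 0 or few in several lines: M6 had 12.7 ± 1.92 CPM (SD, n = 3) and 80-1 had 3 counts, while the resistant lines had 7.24 (EE501F2_089), 8.93 (EE501F2_516) and 3.48 ± 2.84 CPM (EE501F2_641). The plants of EE501F2_641 had 5.44, 0.218 and 4.78 CPM, so that its replicate 2, with 4 counts, was near the susceptible lines. Among the susceptible lines, EE501F2_093 had 4 counts and the other 2 lines had 0.

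Parental labels that were swapped would turn the direction of genes on every chromosome. Outside chromosome 7 the direction was the same for 84.8% of 112 genes changed in both comparisons (exact binomial 95% interval 76.8% to 90.9%). That interval takes linked genes as independent. Other splits of the lines, over all chromosomes, ran from 1 gene alike and 1 opposite to 29 alike and 0 opposite. The sides of each were ordered to give the larger count. Agreement in 1 direction can thus arise without a link to the trait, so the share does not decide about swapped labels. A candidate explanation is a chromosome 7 segment at which the resistant lines carry M6 alleles and the susceptible lines are at the 80-1 state. Among the 27 other genes with strong parental differences in 0 to 5 Mb, the lowest susceptible line median minus the highest resistant line median was -0.039 (95% interval over resampled genes -0.466 to 0.093), so a segment of that length stays open. A shorter segment around the run, and a chance assortment unrelated to the trait, were not tested.

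The other genes with a different effect in the 2 generations are given by their parental minus F2 log2 fold change. Values of genes with 0 counts in a line depend in the same way on the prior count. Among the genes named for the parents, it was 8.55 for g26016, -10.35 for g18288 and -12.39 for g1277. These genes were picked for the largest parental differences, so a smaller difference between the F2 classes follows in part from that choice. The gene g26016 varied within the resistant class, from 1.72 ± 0.660 CPM in EE501F2_089 to 16.3 ± 22.2 CPM in EE501F2_641, whose plants had 6.79, 41.7 and 0.503 CPM. Among those named for the F2 lines, picked for the largest F2 falls, the difference was -3.34 for g23983 and 4.03 for g19481. It was 1.09 for g33589, 1.16 for g27169 and 1.72 for g19953, which all changed in the same direction in the 2 generations; the parental change was the larger at g33589 and the F2 change at g27169 and g19953.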

How the results depend on the processing

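Of 177 values under alternative settings, 148 stayed within 1.5 times of the value reported or on the same side of the threshold. In tests on plants, 12 named genes under 5 settings of normalization, filter, block and method (60 values) kept their direction and their call; they were not run with a line or replicate left out. Of 36 values of F2 lines against parents 33 stayed within 1.5 times, and the others, on only the 6 libraries compared, an alternative chosen after seeing the data, were 2799 (EE501F2_641 and 80-1), 3808 (EE501F2_641 and M6) and 7446 (EE501F2_093 and 80-1). With a minimum of 2-fold, which counts fewer genes by construction, the parents had 4669 genes, the mean of the F2 plants 2221, all 9 pairs 109, and parents and F2 alike 43. Leaving out 1 library of 1 parent gave 6421 to 6952 genes for the parents. With 2 plants in every line in place of 3, the counts were 3999 to 5457 for the mean of the F2 plants, 66 to 219 for all 9 pairs and 27 to 74 for genes changed alike. Leaving out a line leaves 6 pairs, which is less strict than 9, and gave 313 to 1252 genes (418 without EE501F2_516, 1252 without EE501F2_641, 492 without EE501F2_500). The test over lines then called 0 genes, so that g33589, g33597 and g3669 lost their calls, or 13 without EE501F2_641, and the cause was not tested. The plants of EE501F2_641 differ, and in alternatives chosen after seeing the data the parents had 9241 genes without that line, the mean of the F2 plants 10387 and genes changed alike 429, and with only its replicate 1, 2 or 3 the test over lines called 3, 12 and 9 genes. On all lines DESeq2 called 540 genes (14 to 796 in the other splits of the lines) and limma-voom 174. The 3 genes of the test over lines had 1 on chromosome 2 (33.3%, adjusted p = 1, too few to test), while 17.6% to 20.7% of the genes changed in the 6 pairs left without a line lay there, an alternative chosen after seeing the data, as was DESeq2 for genes changed alike and for the chromosomes. The share of chromosome 2 windows that separated the classes, 87.5% of 8, was 100% of 5 in 10 Mb windows, 57.1% of 14 in 2 Mb windows, and 66.7% of 9 with a log2 fold minimum of 1. Replicate numbers did not pair the samples: over 84 same-numbered pairs the mean correlation of deviations was -0.0021, 17 were over 0.1, and 6 of 24 libraries correlated best with their own number. With the replicate block the counts were 7744 for the parents, 6863 for the mean of the F2 plants, 251 for all 9 pairs, 101 for genes changed alike and, by limma-voom, 131 over lines. The gene lists fixed beforehand were not run for lack of gene descriptions. Depth sets the CPM that 3 counts stand for, from 0.0424 CPM in a library of EE501F2_093 to 0.164 CPM in a library of EE501F2_641.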

Other observations

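The distal end of chromosome 12 held 5 genes higher in every resistant line and in 80-1, including g33589 and g33597. They lie within 69.5 kb (49865983 to 49935488), ending 3.66 kb before the end of the last model of the chromosome, and 9 genes were tested in that span, so that 4 between them did not change in all 9 pairs. Levels of g33589 were 32.8 ± 0.804 (EE501F2_089), 32.7 ± 2.89 (EE501F2_516) and 32.8 ± 1.63 CPM (EE501F2_641; SD, n = 3 plants each), against 77.5 ± 4.37 CPM in 80-1 and 4.31 ± 1.03 CPM in M6. The region was chosen after its values were seen.

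A set of 71 genes had at least 1 CPM in every plant of 80-1 and 0 counts in M6, and 46 had the converse. This limit and the 10% levels that follow used CPM without TMM scaling. Of the 71, 9 stayed below 10% of the 80-1 level in all 6 F2 lines and 16 reached it in all 6. Of the 46, 7 and 15 did so relative to M6. The gene g7648 was among those missing, with 20.1 ± 10.3 CPM in 80-1, 3 counts in EE501F2_093 and 0 counts in the other 5 F2 lines. Genes read only in 80-1 reached that level in 76.1% of cases in EE501F2_641, 66.2% in EE501F2_089, 64.8% in EE501F2_516, 60.6% in EE501F2_500, 50.7% in EE501F2_093 and 49.3% in EE501F2_099. For genes read only in M6 the lines were not in the reverse order: 78.3% in EE501F2_099, 71.7% in EE501F2_641, 69.6% in EE501F2_093, 63.0% in EE501F2_089 and EE501F2_500 each, and 60.9% in EE501F2_516.

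Of the tests that follow, the count in 100 kb bins and the splits of the parental and of the line-against-parent comparisons were fixed before their result was seen, and the others were chosen after it. For some of the latter, among them the tests of the segments on chromosomes 7 and 12, the ratios on chromosome 12, the lower genes on chromosome 2, the test of a dominant allele, the neighbouring windows of EE501F2_641 and the splits by chromosome, the form or the bound was changed after a first version had been run. A hypothesis for the genes missing from all F2 lines is that 80-1 carried a second haplotype that was not passed on, but they were not shown to be more frequent among genes read only in 80-1 than among those read only in M6 (odds ratio 0.81, 95% interval 0.245 to 2.78; Fisher's exact test, two-sided, p = 0.785), which leaves it open. Taken over both sets, 63.8% of line-by-gene cases were read (95% interval over resampled genes 58.3% to 69.8%). A single dominant allele segregating at every such gene would leave 0.0286 of the 117 genes below 10% of the parental level in all 6 lines, but 16 were. Counted by 5 Mb windows, since neighbours are linked, every such gene was missing from all 6 lines in 9 of 74 windows (12.2%, exact binomial 95% interval 5.71% to 21.8%), against 0.184% expected even if only 65% of cases were read, which argues against it for the set as a whole. Of the 117 genes 1 had 0 counts in all 6 lines. Few counts, such as the 3 of g7648 in EE501F2_093, do not show that the other missing genes were expressed.

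The excess of changed genes on chromosome 2 was weighed against technical explanations. Loss of 80-1 reads in alignment would lower genes in the resistant lines, and 61.1% of the 54 genes were lower (exact binomial 95% interval 46.9% to 74.1%). The 54 include genes that chromosome 2 would hold without any excess, so this share cannot decide about the excess. Counted by direction, the 33 lower genes were over-represented on chromosome 2 (Fisher's exact test, two-sided, adjusted p = 4.90e-06). The 21 higher genes were not (adjusted p = 0.259). Of the 33 lower genes 75.8% were also lower in 80-1 than in M6 (57.7% to 88.9%) and 1 was called higher there. Loss of 80-1 reads thus stays open. The depth of EE501F2_093 is not needed for the excess, since 20.7% of the genes changed in the 6 pairs without that line lay on chromosome 2 (adjusted p = 5.54e-09). Reads shared between neighbouring models are not needed either, since the odds ratio was 2.75 (1.91 to 3.91) when 100 kb bins were counted. A segregating segment at which the resistant lines are at the 80-1 state is consistent with 6 of 8 windows on chromosome 2, and 4 of 88 elsewhere, that keep every resistant line above every susceptible line with the changed genes left out. That such a segment may carry a locus for resistance is a hypothesis, found and tested on the same 6 lines, and other splits of these lines also gave an excess on 1 chromosome, with a smaller p in 3 of them.

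At the distal end of chromosome 12, reads of 1 source spread over the 5 models would keep their ratios, but between the highest and the lowest of 80-1 and the resistant lines the CPM ratio differed at least 2-fold, beyond the spread between plants, for 10 of 10 pairs of the models (2.44- to 8.92-fold, with 80-1 the highest or the lowest for 7). The 10 pairs share 5 models and are not independent, and the lines compared were the extremes of each pair. In EE501F2_516 the ratio of g33589, at 32.7 ± 2.89 CPM, to another of the models, g33598, was 229 ± 107 (SD, n = 3). There g33598 was near the level of 3 counts, so its ratios in that line rest on few counts. A segment at the 80-1 state may extend beyond the 5 genes: among 16 other genes with strong parental differences in 48 to 50 Mb, the lowest resistant minus the highest susceptible line median was 0.094 (95% interval over resampled genes -0.24 to 0.291), which leaves this open. A shared regulator of the 5 genes was not tested.

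The 3 plants of EE501F2_641 were unlike in parental state. On a linear CPM scale, the median state over 76 genes in 5 to 25 Mb of chromosome 2 was 0.579, 0.926 and 0.461 in its plants, against 0.791 to 0.939 in those of EE501F2_089 and 0.869 to 0.913 in those of EE501F2_516, so the line mean says nothing of the number of copies of a segment. A single mislabelled or mixed library would leave the other pair of plants alike, but even the closest pair of EE501F2_641 differed by 0.227 per window (mean absolute difference, 95% interval over resampled windows 0.195 to 0.267), and the farthest pair of any other line by 0.107. Different genotypes under 1 line name may be the source: the plants' deviations from their line mean were correlated between neighbouring windows (0.384, 95% interval over resampled chromosomes 0.183 to 0.541). Plants of M6 gave 0.335, but a correlation leaves out the size of the deviations. The median range between plants per window was 0.341 in EE501F2_641 and 0.0545 in M6, so the M6 value is no argument against different genotypes. Over whole chromosomes, the SD between plants ran from 0.0432 (chromosome 12) to 0.257 (chromosome 7) in EE501F2_641. It was at most 0.0827 in another F2 line. Variants in the reads were not examined, so different genotypes stay open, as does an error in more than 1 library.

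Other splits of the same libraries or lines into 3 and 3 are 10 in each comparison, too few for a share under 0.05. The parents gave 7847 genes with the real split and at most 0 with another (1 of 10 splits as large). The 12 comparisons of an F2 line with a parent, fitted on their own 6 libraries, gave 2799 to 11987 genes and at most 0 in other splits (1 of 10 each). In all these comparisons another split mixes plants of both lines on each side, which puts the line difference into the spread. The 0 calls were thus nearly fixed beforehand and are no check on the real counts. Over lines, the test on summed counts gave 3 genes and at most 7 in another split (2 of 10 as large), and the mean of plants gave 7007 and at most 10700 (4 of 10). The criterion of all 9 pairs gave 266 and at most 139 (1 of 10), genes changed as in the parents 101 and at most 72 (1 of 10, though as a share of the changed genes 7 other splits were higher), and windows that separate the lines 14 and at most 12 (1 of 10). The chromosome with most changed genes held 54 with the real split (chromosome 2) and at most 41 with another (chromosome 4; 1 of 10). By the smallest adjusted p of a chromosome, 4 of 10 splits were as extreme, with -log10 values of 4.90 for the real split and at most 15.3 for another, so that an excess on 1 chromosome does not by itself point to the trait.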
